A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

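The series holds 2 microarrays of the yeast Saccharomyces cerevisiae, strain BY4741, a laboratory strain that lacks HIS3, LEU2, MET17 and URA3. Per the labels, cells were grown in rich medium at 24 °C, diluted to an optical density of 0.2 and regrown, and the culture was divided in 2. Congo Red, a dye that binds chitin and glucans and disturbs the cell wall, was added to 1 part at 30 µg/ml, and cells were collected at 0 h. Each array carried total RNA of a treated and an untreated part. Array 1 held untreated RNA in channel 1 and Congo Red RNA in channel 2, and array 2 held them the other way round, per the labels. The dyes, the scanner, the image software, the normalisation and whether the arrays hold RNA of separate cultures are not given in the sources used here.

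The deposited values are log2 ratios of the 2 channels, as read from the values themselves: 2 to the power of each measured value was a ratio with 3 decimals in 100% of spots on both arrays, within 0.01 thousandths (times the ratio where it is over 1). The ratios had not been centred. The median over spots was 0.48 on array 1 and −0.33 on array 2, and over genes it was 0.51 and −0.32. The base of the log was thus settled by the values, whereas any further scaling, any background correction and the direction of the ratio (which channel was divided by which, and whether one array had already been turned) stay unknown. Of 12800 spots, 1845 (14.4%) on array 1 and 974 (7.61%) on array 2 had no value, and another 81 and 7 held a ratio of 100000, read here as a placeholder and left out. Ratios that equal a fraction of whole numbers up to 12 after both are rounded to 3 decimals made up 9.09% of measured spots on array 1 and 6.80% on array 2, against 2.30% and 3.91% from neighbouring ratios by chance. Spot intensities were not analysed here, so signal over background is unknown for every spot. The number of arrays limits the precision.

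Spots were named through the platform's probe table. There, 11138 spots had 1 gene symbol, 0 had several and 1662 had none. The named spots covered 5539 genes, of which 5510 had 2 spots, 28 had 4 and 1 had 6. Symbols were brought up to date through Entrez identifiers in a RefSeq gene table of the R64 assembly, which held 5534 of the 5539 and which served only for names and gene lengths. Spots of a gene were averaged on each array, and each array was centred on its median over genes. The 4951 genes with a value on both arrays were analysed.

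Both arrays form 1 group with exchanged channels, so 2 contrasts were fitted with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The treatment contrast is the mean of array 1 and array 2 with the sign of array 2 turned, and it is large for genes whose centred ratios have opposite signs. The channel contrast is the mean of both centred arrays without turning, and it is large for genes whose centred ratios have the same sign on both. If one array was turned before deposit, the contrasts exchange their meaning. Signs are therefore given as on array 1, and no direction of treated over untreated is stated. Each gene left 1 residual degree of freedom. Nothing says that the arrays hold separate cultures, so p-values of single genes measure only the spread between these arrays, which may be technical.

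A total of 21 gene lists, fixed before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Of these, 20 were written out by symbol and the ribosomal protein list was taken by symbol pattern. They cover cell wall integrity targets, Slt2 pathway components, environmental stress genes, heat shock proteins, ribosome biogenesis, ribosomal proteins, glycolysis and ethanol, the respiratory chain and TCA cycle, histones, G1/S genes, daughter-cell and M/G1 genes, mating genes, the phosphate regulon, Gcn4 amino acid biosynthesis, sulfur and methionine, ergosterol, iron and copper, hexose transport and glucose repression, the proteasome, seripauperin and telomeric families, and the deleted marker genes of BY4741. Some lists overlap, and the largest overlaps were 5 genes. With the preset correlation, camera compares list members with other genes. Its p-values therefore treat genes as replicates and do not measure the spread between arrays. Bootstrap intervals of list medians likewise resample genes. Paired copies, such as the histone genes HTA1 and HTA2 or the A and B copies of ribosomal protein genes, count as separate genes. Whether their spots tell them apart was not examined.

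Named genes followed a rule fixed in advance. For each contrast and side, genes past the threshold would be named, and where fewer than 5 passed, the 10 genes with the largest smaller ratio of the 2 arrays were named as values. The 2 highest and 2 lowest members of each list, the deleted marker genes, SLT2, RLM1, CRH1, PIR3 and FKS2 (now GSC2) could also be named.

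The scripts were tested on simulated data. In 20 simulated treatment contrasts of 4951 genes with 200 changed genes, limma called 0% of genes changed by a log2 of 1, 0.6% at 2, 40.6% at 4 and 85.6% at 8. A simulated ribosomal protein shift of −0.5 was called in 20 of 20 simulations with the preset correlation (camera adjusted p under 0.05). With an estimated correlation it was called in 1 of 20, even by unadjusted p under 0.05. An estimated correlation thus had little power with 1 residual degree of freedom. With the preset correlation 1 of 420 unchanged lists was called. Simulated genes varied independently, so this count does not show how often lists of correlated genes would be called falsely.

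Alternatives fixed in advance were no centring, scaling to a common median absolute deviation, quantile normalisation, another summary of a gene's spots, filters on spot number and spot disagreement, spots kept with the array as a block, a robust prior, a threshold of 0.1, no turning of array 2, rank-based camera, and each array left out. Centring each run of 400 consecutive spot numbers, keeping placeholder ratios, leaving out small-fraction ratios and leaving out the 4 runs with the lowest array 1 medians were added after the data were seen. Figures were drawn with matplotlib 3.10.9.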

Results

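Expression was compared by 2-colour microarray between Congo Red and untreated parts of yeast culture that had been divided, at 0 h of exposure, on 2 arrays with exchanged channels. It asks whether the parts differed when the dye was added. Whether the arrays hold RNA of separate cultures is not given, so n counts arrays. Each array had 12800 spots, of which 10874 were measured on array 1 and 11819 on array 2, and 4951 genes had a value on both.

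Ribosomal protein genes, and histone genes mainly on array 2, stood apart from other genes. After centring, their medians had opposite signs on the 2 arrays, as a difference between the RNAs would give if both ratios ran in the same channel order. Before centring, when the medians over all genes were 0.51 and −0.32, the medians of both lists were positive on both arrays. In limma's camera test with the preset correlation, which treats genes as replicates, the adjusted p was 8.14e-16 for ribosomal protein genes and 0.00298 for histones. Neither call held with an estimated correlation (adjusted p = 0.95 for both). The 132 ribosomal protein genes, which encode the subunits of the ribosome, had a median log2 ratio of −0.42 on array 1 and 0.56 on array 2, and 110 of them were negative on array 1 and positive on array 2, whereas 30.4% of all genes had that pattern. In the treatment contrast their median was −0.49 ± 0.10 (SD between arrays, n = 2). RPS22A (YJL190C) was at −1.73 on array 1 and 0.69 on array 2, and RPL14A (YKL006W) at −1.49 and 0.68. At the other end of the list were RPS1B (YML063W), at 3.34 and −0.24, and RPS19A (YOL121C), at 0.39 and −0.77. The 10 histone genes had medians of −0.32 and 0.64, a treatment contrast of −0.53 ± 0.23 (SD between arrays, n = 2), and 9 of 10 had this pair of signs. Paired copies such as HTA1 and HTA2 are counted as separate genes here, so the members may not be independent. Among random lists of the same size the histone median was at percentile 8.56 on array 1 and 0.02 on array 2 after turning. The histone shift thus rests mostly on array 2. After the trend with gene length was subtracted the histone median was −0.27 (95% bootstrap interval −0.33 to −0.21). Among them HTA2 (YBL003C) was at −0.34 and 0.83 and HTA1 (YDR225W) at −0.48 and 0.68, whereas HHO1 (YPL127C), the linker histone, was at 0.23 and 0.76.

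Without centring, the median of all genes in the treatment contrast was 0.41, and the medians were −0.075 for ribosomal protein genes and −0.12 for histones, so the shifts are relative to other genes. Short genes shared the same side: among genes outside the ribosomal protein list with a length that is a multiple of 3, the median was −0.27 for the 363 genes up to 450 bases and 0.09 for the 1940 over 1500 bases. Among 39 abundant genes outside the lists it was −0.38.

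**Figure D1:**
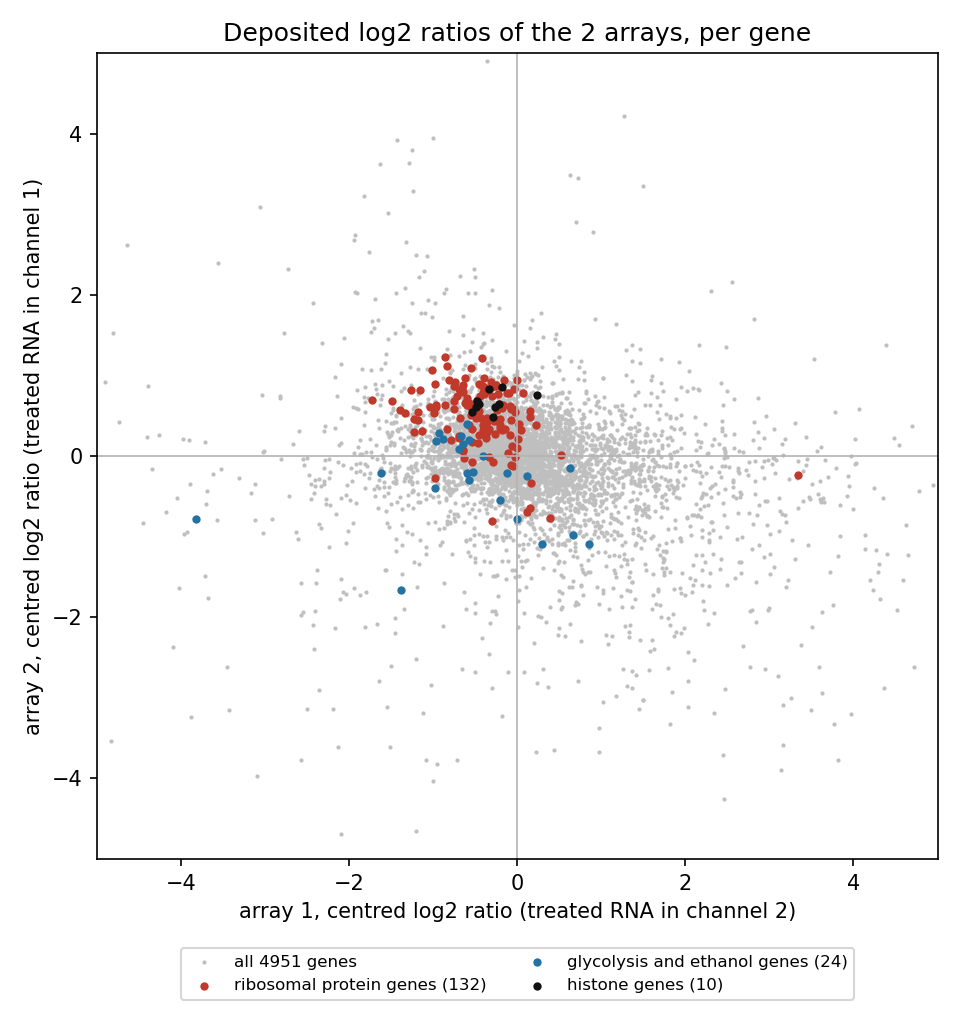
Centred log2 ratio of each of the 4951 genes on array 1 (x axis) and array 2 (y axis), with 132 ribosomal protein genes, 24 glycolysis and ethanol genes and 10 histone genes coloured. Ribosomal protein genes gather at −0.42 on array 1 and 0.56 on array 2 (medians), and 29 genes lie outside the axes, which end at 5.

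The cell wall genes that respond to Congo Red through the Slt2 kinase did not stand apart at 0 h. The 32 measured targets of this pathway had a median of −0.01 in the treatment contrast (limma camera adjusted p = 0.915), with 16 members on each side of 0, and 0 members passed the threshold either over all genes or adjusted over the list alone. CRH1 (YGR189C), a chitin transglycosylase, was at 2.14 on array 1 and −0.75 on array 2, PIR3 (YKL163W), a cell wall protein, at 0.85 and −1.30, and RLM1 (YPL089C), the transcription factor of the pathway, at 0.83 and −0.26. PST1 (YDR055W) was at 3.47 and −0.50, and GSC2 (YGR032W), a glucan synthase subunit, was at −0.82 and −0.20. SLT2 itself was measured by 1 spot on array 1 only. The 18 Slt2 pathway components had a median of 0.11 (adjusted p = 0.578), and among them SLG1 (YOR008C), the sensor also known as WSC1, had a treatment contrast of 1.01 ± 0.02 (SD, n = 2).

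Other lists in the treatment contrast had adjusted p-values from 0.115 to 0.915 in camera. The 37 respiratory chain and TCA cycle genes had a median of −0.25 (adjusted p = 0.115), with QCR10 at −3.62 on array 1 and −0.23 on array 2 and IDH2 at 0.31 and −0.96. This list passed the threshold when runs of spots were centred separately (adjusted p = 0.0143 with the preset correlation), and with whole arrays centred its adjusted p was 0.95 with an estimated correlation. The 30 hexose transport and glucose repression genes had a median of 0.20 (adjusted p = 0.153), with MLS1, malate synthase, at 7.85 and −3.38 and HXT13 at 2.28 and −1.61. Medians were 0.17 for daughter-cell and M/G1 genes, 0.09 for G1/S genes, 0.04 for the phosphate regulon, 0.03 for heat shock proteins, 0.02 for iron and copper genes, 0.01 for ribosome biogenesis and 0.0016 for environmental stress genes. On the other side were glycolysis and ethanol genes at −0.20, the deleted marker genes at −0.19, the proteasome at −0.16, seripauperin and telomeric families at −0.15, mating genes at −0.14, sulfur and methionine genes at −0.13, ergosterol genes at −0.12 and Gcn4 amino acid genes at −0.11. For cell wall targets, sulfur and ergosterol genes the mean had the opposite sign to the median, for environmental stress genes the mean and the test were negative with a positive median, and for G1/S and iron genes the test alone was negative. Among the genes BY4741 lacks, HIS3 was at −0.85 and 0.47, LEU2 at 0.03 and −0.05, and MET17 at −0.75 and −0.37, and URA3 was measured on array 1 only.

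**Figure D2:**
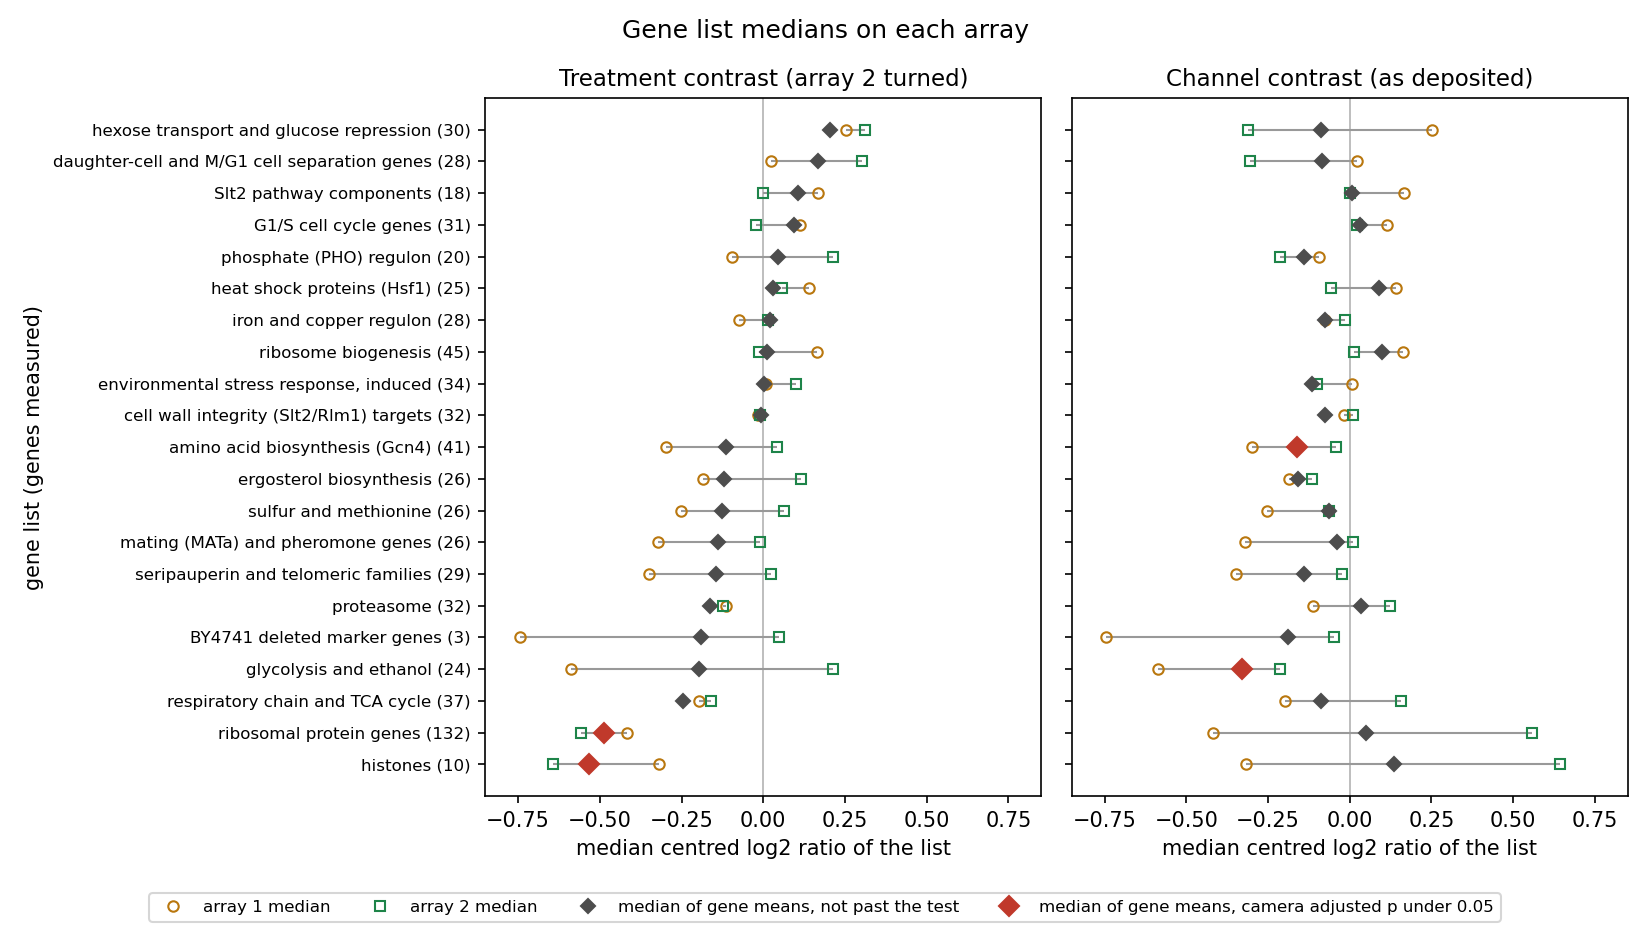
Median centred log2 ratio (x axis) of each of the 21 gene lists (y axis, with genes measured) on array 1 (circles) and array 2 (squares). Diamonds give the median over gene means, red where camera with the preset correlation passed the threshold. The treatment contrast has array 2 turned, and the channel contrast has both centred arrays in their deposited direction. Ribosomal protein genes and histones pass in the treatment contrast, and glycolysis and Gcn4 amino acid genes in the channel contrast, but 0 lists pass with an estimated correlation (adjusted p = 0.95 and 0.795).

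No single gene passed limma's test in the treatment contrast (0 of 4951, lowest adjusted p = 0.536), and 398 had an unadjusted p under 0.05, where chance gives 247.55. Of the 398, 288 were positive on array 1 and 110 negative. The genes with the largest ratios on both arrays are given as values. With array 1 positive and array 2 negative they were YIL102C (3.79 ± 0.03, SD, n = 2, as for the values that follow), MLS1 (5.62 ± 3.16), YCR101C (3.55 ± 0.31), PGM2, a phosphoglucomutase (3.59 ± 0.54), YNL194C (3.33 ± 0.24), SPG4 (3.37 ± 0.30), HCS1, a DNA helicase (3.51 ± 0.54), YPQ2 (3.13 ± 0.05), VMS1 (3.13 ± 0.18) and AGP3, an amino acid permease (3.29 ± 0.48). With the opposite signs they were ROF1 (−3.08 ± 0.02), RIB2, a riboflavin synthesis enzyme (−4.23 ± 1.69), AFB1 (−3.63 ± 1.43), ARG1, argininosuccinate synthetase (−2.98 ± 0.83), DCG1 (−2.52 ± 0.29), MTO1 (−2.31 ± 0.53), GAL80, the repressor of the galactose genes (−2.34 ± 0.58), PGA3 (−1.98 ± 0.08), YDR514C (−1.97 ± 0.08) and CRC1, a mitochondrial carnitine carrier (−2.17 ± 0.38). Of these 20 genes only YPQ2 and AGP3 had all 4 spots measured.

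At 2-fold or more on both arrays were 264 genes with opposite signs, against 83.8 if the arrays were independent, and 83 with the same sign, against 67.7. The same-sign excess depended on the setting. It was absent at 1.5-fold (199 against 279.7) and with 2 or more spots on each array (23 against 23.9). It was larger with the spot closest to a deposited 0 (61 against 33.6), without disagreeing spots (49 against 27.1), with runs of spots centred separately (79 against 51.02) and without the 4 lowest runs (70 against 45.2). Opposite-sign genes stayed above independence in all of these, from 596 against 289.9 at 1.5-fold to 135 against 32.4 without disagreeing spots. Of the 264, 203 were positive on array 1 and 61 negative, and without centring the split was 382 and 27. Only 33 and 8 genes had every spot past this minimum. Across genes, which are not independent replicates, the deposited ratios of the 2 arrays had a Pearson r of −0.243 and a Spearman rho of −0.281. Across spots within the 32 runs of 400 consecutive spot numbers, r went from −0.441 to 0.080 and was negative in 27 runs.

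The channel contrast is the mean of both centred arrays without turning. There, camera with the preset correlation called glycolysis (adjusted p = 0.000861) and Gcn4 amino acid genes (adjusted p = 0.0297). Neither call held with an estimated correlation (adjusted p = 0.795 for both), and the amino acid call was also lost without centring (adjusted p = 0.123), where the median of all genes in this contrast was 0.12, and with the spot closest to a deposited 0 (adjusted p = 0.0536). The 24 glycolysis and ethanol genes had a median of −0.59 on array 1 and −0.21 on array 2, with a median of −0.33 ± 0.26 over gene means (SD between arrays, n = 2). Of the 24, 23 had a negative mean, but only 11 were negative on both arrays, against 19.6% of all genes. ADH4 (YGL256W) was at −3.83 and −0.79 and GPD1 (YDL022W) at −1.38 and −1.66, whereas GPD2 (YOL059W) was at 0.62 and −0.15. The 41 Gcn4 amino acid genes had medians of −0.30 and −0.041, with a median of −0.16 ± 0.18 over gene means (SD between arrays, n = 2). Before centring, when the medians over all genes were 0.51 and −0.32, the median of this list was positive on array 1 and negative on array 2. Of the 41, 37 had a negative mean, but only 14 were negative on both arrays. Among random lists of the same size their median was at percentile 0.73 on array 1 and 34.3 on array 2, so the shift rests on array 1. TRP4 (YDR354W) was at −1.80 and 0.05, and SER3 (YER081W) at 1.34 and −0.55.

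The other 19 lists had adjusted p-values from 0.165 to 0.87 in the channel contrast, with medians from −0.19 for the deleted marker genes to 0.14 for histones. Ribosomal protein genes had a median of 0.05 and cell wall targets one of −0.08. For Slt2 pathway components and heat shock proteins the mean and the test were negative with a positive median, and for mating genes the mean was positive with a negative median and test. No gene passed limma's test (0 of 4951, lowest adjusted p = 0.9997), and 89 had an unadjusted p under 0.05, fewer than the 247.55 that chance gives. The positive genes with the largest ratios on both arrays were VMA22, an assembly factor of the vacuolar ATPase (5.16 ± 2.16, SD, n = 2, as for the values that follow), PFS1 (2.36 ± 0.29), YIL175W (2.18 ± 0.18), GAL2, the galactose permease (2.26 ± 0.79), YNR064C (2.42 ± 1.31), SWT21 (2.88 ± 2.13), FYV8 (1.77 ± 0.56), PKH2 (1.37 ± 0.007), EUC1 (1.92 ± 0.80) and SET5 (1.39 ± 0.09). The negative ones were MRH4 (−4.19 ± 0.91), ITT1 (−3.56 ± 0.46), DMA1 (−3.29 ± 0.19), MMT1 (−3.54 ± 0.62), GEP5 (−3.03 ± 0.59), ELM1 (−3.17 ± 0.84), AIF1 (−2.82 ± 0.45), GDB1, the glycogen debranching enzyme (−2.41 ± 0.02), ACS1, acetyl-CoA synthetase (−3.23 ± 1.23) and YOL075C (−2.63 ± 0.39). Of these positive and negative genes only EUC1, SET5 and ACS1 had all 4 spots measured.

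The arrays differed in width. The SD of the centred log2 ratios was 1.17 on array 1 and 0.79 on array 2, and 74.4% and 88.0% of genes lay within 2-fold. Duplicate spots of a gene gave an error of 0.78 on array 1 and 0.57 on array 2, from the SD of their differences. From the median absolute deviation the error was 0.26 and 0.18, against a spread over genes of 0.72 and 0.49 by that measure. Duplicate spots had a correlation of 0.50 on array 1 and 0.49 on array 2, and on array 1 18.3% of genes had spots over 1 log2 unit apart. Medians of runs of 400 consecutive spot numbers went from −1.12 to 0.49 on array 1 and from −0.22 to 0.26 on array 2.

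**Figure D3:**
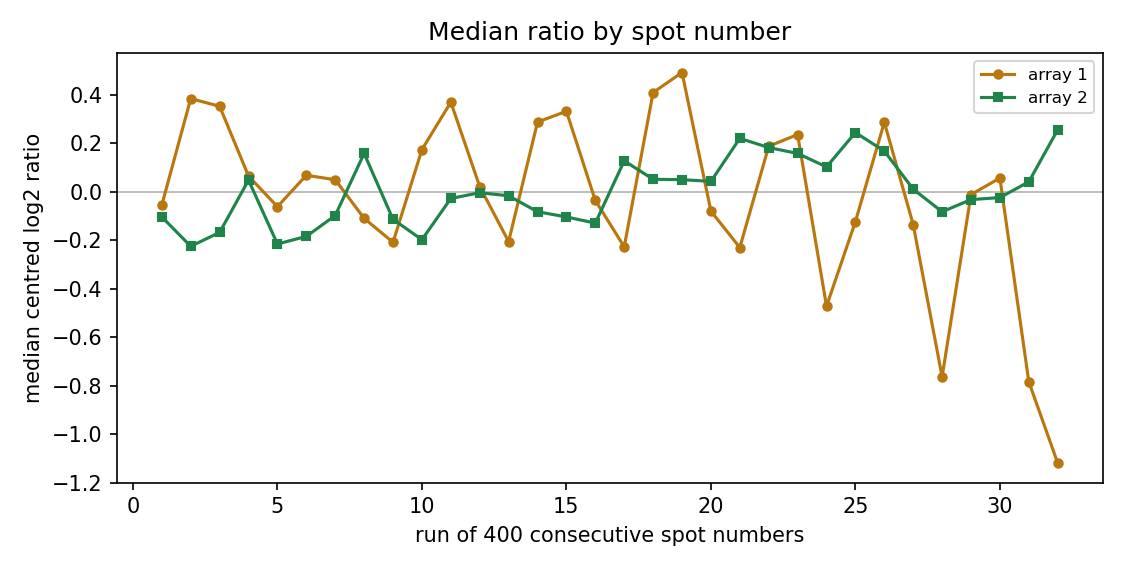
Median centred log2 ratio (y axis) of each of 32 runs of 400 consecutive spot numbers (x axis) on array 1 (circles) and array 2 (squares). Array 1 is at −1.12 in run 32, and array 2 stays between −0.22 and 0.26.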

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

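Separate centring of runs, kept placeholders, small-fraction ratios left out and the 4 lowest runs left out were chosen only after the data were seen, as were the settings of scaling, spot summary and spot filters where they were applied to lists and to counts at 2-fold. The count of genes past limma's threshold was 0 in both contrasts under every setting with a test. With 1 array left out no test is possible, and genes at 2-fold on the remaining array numbered from 592 to 1267. With an estimated correlation 0 lists passed in either contrast, with medians still −0.49 for ribosomal protein genes, −0.53 for histones, −0.33 for glycolysis and −0.16 for amino acid genes. In the channel contrast 1 list passed without centring, where amino acid genes were at −0.066 (adjusted p = 0.123), and 1 with the spot closest to a deposited 0, where they were at −0.13 (adjusted p = 0.0536). The cause was not tested. In all other settings with a test these 4 lists kept their side and passed. At the preset correlation the respiratory chain list passed with runs centred (adjusted p = 0.0143) and without the 4 lowest runs (adjusted p = 0.0472), and seripauperin genes passed by ranks in the channel contrast (adjusted p = 0.0374).

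Opposite-sign genes at 2-fold numbered 409 without centring, 158 with the spot closest to 0, 126 with 2 or more spots on each array, 135 without disagreeing spots, 596 at 1.5-fold and 33 with all spots past the minimum. Same-sign genes numbered 23 with 2 or more spots (23.9 for independent arrays), 49 without disagreeing spots (27.1), 199 at 1.5-fold (279.7) and 8 with all spots, so their excess was lost in the first and turned at 1.5-fold. Stricter filters test fewer genes. Of 1856 named gene values under alternatives, 1718 stayed within 1 SD of the main value, 138 moved further and 33 changed sign. The SD is that of the gene between the 2 arrays, which was large for many named genes. Genes that a setting left out were not counted, so these counts say little about stability. Spot brightness over background was not analysed here, so its limit is unknown.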

Other observations

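The genes named in the paragraph on spots that agree, the length medians of histones, the values of placeholder and unnamed spots, both later versions of the length test and the test on ratios that were already turned were chosen only after the result was seen. The abundance and dim-spot tests were written before their results. Centring runs of spots, used for the position test, was chosen after the data were seen but before its effect on these patterns was.

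Among 2228 genes whose spots were all measured and lay within 0.5 log2 units of each other, with no ratio equal to a small fraction, 10 were at 2-fold or more on both arrays with opposite signs and 2 with the same sign. Values are given for array 1 and then array 2. Positive on array 1 and negative on array 2 were AAD15 (mean of 1.60 after array 2 was turned), HOL1, a transporter (1.53 and −1.42), PMA2, a plasma membrane proton pump (1.40 and −1.77), HFL1 (1.09 and −1.24), DED81, asparaginyl-tRNA synthetase (1.07 and −1.04), and PYK2, a pyruvate kinase (1.02 and −1.66). With the opposite signs were PDE2, a cAMP phosphodiesterase (−1.66 and 1.69), TOM6, a part of the mitochondrial import pore (−1.57 and 1.15), PRE5, a proteasome subunit (−1.56 and 1.26), and RPS28A (−1.02 and 1.06). EUC1 (2.49 and 1.36) and MRPL32 (1.30 and 1.32) had the same sign on both.

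The 132 ribosomal protein genes had a median of −0.49 in the treatment contrast, and centring each run of 400 spots separately left −0.45 (95% bootstrap interval −0.49 to −0.39). This argues against shifts between runs of spots as the whole cause. Gene length was tested in 3 versions: all 132 members at their table length gave −0.45, which decides nothing because only 58.3% of them have a length that is a multiple of 3 and the others may span introns; the 77 that do went from −0.51 to −0.39 (−0.52 to −0.34), and the 47 of these under 800 bases from −0.58 to −0.36 (−0.53 to −0.32). In both later versions the interval after the correction stayed on the same side of 0. A length that is a multiple of 3 may still span an intron, so these versions cannot exclude length, which stays open for all members. Abundance may account for the shift, since 39 abundant genes outside the lists had a median of −0.38 (−0.57 to −0.25). That set leaves out all members of the fixed lists, among them the glycolysis genes. Those did not have opposite signs, with medians of −0.59 on array 1 and −0.21 on array 2, so abundance stays open. Translation genes among the 39 were mostly negative, with SUI1 at −0.80, TEF1 at −0.72, TEF2 at −0.71, HYP2 at −0.64 and EFT1 at −0.28. On the positive side were STM1 at 0.46, EFT2 at 0.42, YEF3 at 0.16 and PAB1 at 0.10. The 39 genes therefore cannot separate abundance from a shift of translation genes. A growth difference between the parts was not tested apart from abundance and stays open. A channel effect in ratios already turned before deposit cannot be told apart from a difference between the RNAs, because a correlation of −0.243 between the arrays is what either would give, and the treatment stays open as untested.

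An excess of opposite-sign genes at 2-fold, 264 against 83.8 for independent arrays, was also weighed. Genes with complete, agreeing spots still gave 10 (exact Poisson 95% interval 4.80 to 18.4) against 2.02. This argues against missing, disagreeing or small-fraction spots as the cause of all of it. Spot intensities were not analysed and dim spots may also agree, so the test cannot decide on dim spots. The 10 genes are few of the 264, and dim spots may still account for most of the count. Centring each run of spots left 234 (205 to 266) against 70.4, which argues against shifts between runs as the whole cause. The correlation of the arrays within runs went from −0.441 to 0.080. Centring does not remove such differences, so other effects of position stay open. A difference between the RNAs and a channel effect in turned ratios both stay open.

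The glycolysis list, at −0.33 in the channel contrast, kept −0.28 (95% bootstrap interval −0.38 to −0.24) with runs centred separately. This argues against shifts between runs of spots as the whole cause. Abundance cannot be told apart from other causes, because the 39 abundant genes had a median of −0.11 (−0.21 to −0.05), too wide to decide. A dye effect specific to these genes and, had an array been turned before deposit, a difference between the RNAs stay open as untested.

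The 10 histone genes went from −0.53 to −0.27 (95% bootstrap interval −0.33 to −0.21) after the length trend was subtracted. Of 63 placeholder spots of array 1 with a value on array 2, 43 (68.3%, Clopper-Pearson 95% interval 55.3% to 79.4%) were below the array 2 median. Among 1266 spots without a gene name and with a value on both arrays, 100 were at 2-fold on both with opposite signs and 24 with the same sign.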
